A study of Mus musculus with 27 samples.

How the data were processed

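Whole-genome bisulfite libraries of mouse embryonic stem cells on D0 and of epiblast-like cells on D1 and D2 were analysed for the lines TET_WT, TET_KO and DNMT_WT, with 3 replicates for each line and day. Per the labels, DNA was sheared, made into libraries with enzymatic end repair and adapter ligation, bisulfite converted and amplified with a uracil-tolerant polymerase. The authors trimmed reads with Trim Galore 0.6.6 and cutadapt 2.3 and called methylation with Bismark 0.23.0 on GRCm38, and deposited the methylation of CpGs as a percent for each library and window, on a scale from 0 to 100. The windows are named as 100-CpG windows. How the authors filled them, whether 100 counts sites or cytosines of both strands, and which coverage filter was applied are not given. The labels give no depth per library, and the deposited table holds no counts, so no depth and no binomial interval can be stated, and a window filled by few reads cannot be told from a well-covered window. Libraries of the DNMT knockout line and of embryoid bodies were not used here.

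The table holds 453245 windows, 453239 nuclear and 6 mitochondrial, with a median length of 5050 bp and 5th and 95th percentiles of 1361 and 11845 bp. Tests used the 444250 nuclear windows with a value in every library. Percentages were used as deposited. No pair of libraries shared more than 0.0111% identical values. Values less their group means, compared between libraries with the same replicate number, had correlations of -0.0549 to 0.0570 over 108 pairs, so replicate numbers were not used as pairs. Groups, contrasts, gene lists, window classes, thresholds and alternatives were chosen before the data were examined, except where the text says otherwise.

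Windows were tested with the model of limma 3.58.1 (lmFit and eBayes with trend, R 4.3.3) with a mean for each of the 9 groups over all 27 libraries, which left 18 residual degrees of freedom, a median residual SD of 2.60 points and a median prior of 9.33 degrees of freedom. The model was computed with matrix code checked against limma. A window or gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 percentage points. Contrasts were D0 to D1 and D1 to D2 within each line, TET_KO and DNMT_WT each against TET_WT on each day, and the difference of the D0 to D2 gains of TET_KO and of DNMT_WT from that of TET_WT. Genome means were tested by exact permutation, 3 against 3 within a line or day, and over 3 strata with 8000 arrangements. Means of window classes and gene lists were tested with limma, gene lists against other genes with camera (preset correlation 0.01, and again with an estimated correlation), and overlaps and shares with Fisher tests, in which windows are not independent replicates. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fit was tested on simulated data with the residual spread of each window pooled over the 9 groups. Differences of 10, 15, 20 and 30 points between TET_KO and TET_WT on D2 were given to 50 windows each. They were called in 20, 44, 49 and 50 windows, with 4 unchanged windows called and 0 of a wrong sign. Noise was drawn for each window alone, so shifts shared by the windows of a library were left out. Few windows were changed there, so the cut of the adjusted p was stricter than in the data, where most windows differed. The shares called and the 4 unchanged calls therefore do not carry over to the tested data.

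The gene table of the build gives positions without strand, so the planned window at the transcription start could not be placed, and neither the class of windows at starts nor start-based lists were run. A gene is instead the mean of the windows overlapping its body, a measure planned in advance, and 59.5% of windows lay in gene bodies. A further measure, the shorter and so more CpG-dense of the windows at the ends of the gene, was added after the table was seen. Windows can hold more than 1 gene, and 13 listed genes lay within a single window. There were 12 lists: naive pluripotency, formative and primed epiblast, germline genes, imprinted loci, haematopoietic and endothelial regulators, neuroectoderm, mesoderm and endoderm, primitive endoderm and trophoblast, Hox genes, DNA methylation machinery, 2-cell-like genes, and ubiquitously expressed genes, with 380 genes measured. The 2-cell-like genes are multi-copy, which leaves their mapping uncertain.

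Genes and windows were named by rule. For TET_KO against TET_WT on each day, for the difference of their gains, and for D1 to D2 in TET_WT, the text could name for each list the 4 called members with the largest absolute difference (2 members as values only where fewer than 2 were called), and the 10 called windows with the largest difference in each direction whose replicates did not overlap. The Tet and Dnmt genes and Uhrf1 could always be named. For other contrasts the limits were 2 members and 5 windows. A gene named in 1 contrast may also be given by its levels in other groups, and names chosen after their values were seen are said to be so. A result for 1 window that the rule allows is not reported here. Alternatives were a logit scale in log2 with 1 percent added to the methylated and the unmethylated part, a replicate block, other minimum differences, centring of each library on its median, other window filters, other reference lines, medians, and each library left out in turn.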

Results

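Whole-genome bisulfite sequencing measured DNA methylation in mouse embryonic stem cells kept in the naive state with 2i and LIF (D0) and after 1 and 2 days of conversion to epiblast-like cells (D1 and D2). Libraries of 3 lines were used here. TET_KO carries, per the labels, a triple knockout of Tet1, Tet2 and Tet3, the enzymes that oxidise methylated cytosine, and TET_WT is its parental line. DNMT_WT is the wild-type parent of a different knockout line, which was not analysed here. Each line had 3 libraries on each day, giving 9 groups and 27 libraries. Methylation was given as a percentage in windows named as holding 100 CpGs, with a median length of 5050 bp on GRCm38, and 444250 windows had a value in every library. The table used holds percentages without counts, so the depth behind each value is unknown and no counting interval is given. Counts of genes that rose, fell, or were higher or lower are of those past the adjusted p by at least 10 points, unless any size is stated. Levels are means ± SD of 3 libraries, differences are percentage points ± SE, and a gene's level is the mean over the windows overlapping its body. SEs of differences in genome means use the groups compared, while SEs from limma pool the spread of the 9 groups. In class and list means TET_WT on D2 varied most, so limma SEs that involve it are too small there. Bisulfite conversion does not separate 5-methylcytosine from 5-hydroxymethylcytosine.

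The time course asked how methylation changed as cells left naive pluripotency. The genome rose in methylation in every line, from 25.5% ± 0.387 on D0 through 33.3% ± 1.69 on D1 to 52.5% ± 2.59 on D2 in TET_WT. DNMT_WT began almost unmethylated at 3.20% ± 0.0642, reached 13.6% ± 0.267 on D1 and came close to TET_WT on D2 at 49.6% ± 0.425. TET_KO began at the level that TET_WT reached only on D2, with 51.7% ± 1.10 on D0, 59.2% ± 0.604 on D1 and 70.8% ± 1.17 on D2. The larger step fell between D1 and D2 in each line, with 19.3 ± 1.79 points in TET_WT, 36.0 ± 0.290 in DNMT_WT and 11.6 ± 0.761 in TET_KO. The D0 to D1 steps were 7.79 ± 1.00, 10.4 ± 0.159 and 7.49 ± 0.725 points in the same order. In each line and step all 3 later libraries lay above all 3 earlier libraries, which gives an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. With the day labels permuted within each line over the 3 lines together, the mean rise was 8.57 points from D0 to D1 and 22.3 from D1 to D2, each with a two-sided exact permutation p of 0.00025, the smallest that 8000 arrangements allow. TET_WT replicate 2 stood apart on 2 days, at 31.3% on D1 against 34.3% and 34.2%, and at 55.4% on D2 against 51.6% and 50.5%.

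**Figure D1:**
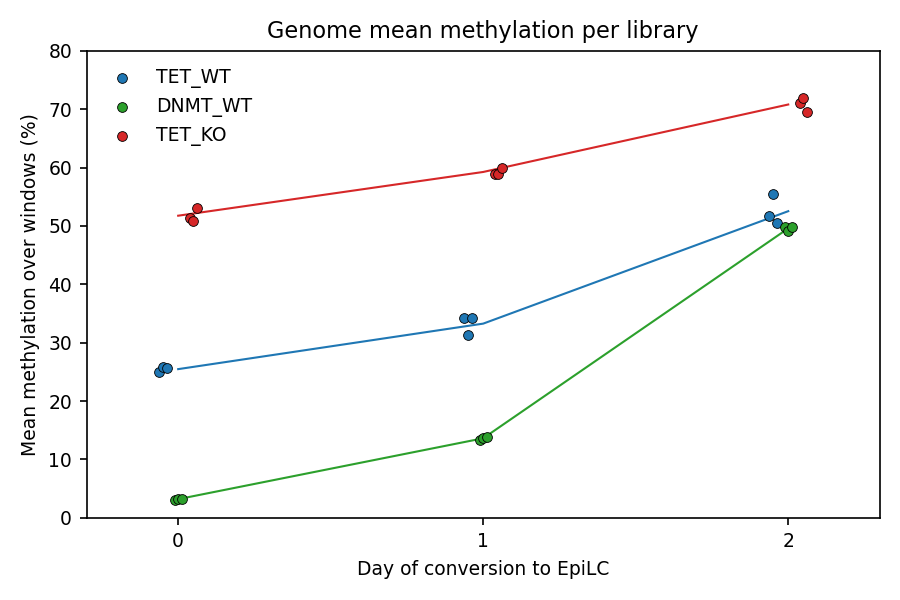
Mean methylation over the tested windows in percent (y axis) against day of conversion (x axis), with a point for each of the 27 libraries and a line through the mean of 3 libraries per group. TET_KO rose from 51.7% to 70.8%, TET_WT from 25.5% to 52.5% and DNMT_WT from 3.20% to 49.6%.

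In TET_WT, genes of the naive network gained methylation mainly on the second day. Nanog, a core pluripotency factor, stood at 4.43% ± 0.834 on D0, 8.92% ± 0.638 on D1 and 28.8% ± 2.86 on D2. From D1 to D2, 23 of 30 naive pluripotency genes rose, against 19351 of all 21434 genes. The median rise of the list was 19.3 points over gene bodies and 4.22 at their CpG-dense end, where that of all genes was 10.2. Tfcp2l1, a transcription factor of the naive state, rose by 31.0 ± 1.29 points, Pecam1 by 30.7 ± 1.13, Esrrb by 27.9 ± 1.29 and Jam2 by 26.5 ± 1.09. Of the formative and primed epiblast genes 17 of 31 rose, led by Lef1, an effector of Wnt signalling, at 21.9 ± 1.03, and Cdh2, which encodes N-cadherin, at 21.8 ± 1.12. Germline genes rose in 49 of 50 cases, among them Majin, a gene of meiotic telomere attachment, at 26.2 ± 1.36, and Tdrd1 of the piRNA pathway at 24.6 ± 1.32. Among the imprinted loci 26 of 36 rose, with Ddc at 24.4 ± 1.09 and Plagl1 at 23.1 ± 1.11. Each of the 12 lists rose in percent, yet each lay below the shift of the library medians, which was 22.4 points, so that all 12 directions turned negative after each library was centred on its own median. The mean of all windows, at 19.3 points, lay below that shift too.

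The same step raised 38 of 48 haematopoietic and endothelial regulators, with a list mean below the median shift when centred, although the genes named next lay above it. Etv6, a regulator of blood stem cells, rose by 27.4 ± 1.11 points, Kit, the receptor of stem cell factor, by 26.1 ± 1.23, and Gata1, a factor of red cell development, by 25.9 ± 1.36. Mesoderm and endoderm genes rose in 15 of 28 cases, with Tbx6 of the paraxial mesoderm at 29.6 ± 2.63 and Hnf4a at 25.3 ± 1.32, and primitive endoderm and trophoblast genes in 17 of 24, with Sparc, a matrix protein, at 28.1 ± 1.32. Of the neuroectoderm genes 5 of 28 rose, with Pax7 at 17.7 ± 0.978 and Tubb3, a neuronal tubulin, at 16.8 ± 1.36, and of the Hox genes 2 of 39 rose, Hoxc4 by 14.9 ± 0.965 and Hoxd4 by 13.3 ± 1.38, all of them below the median shift once centred. At any size 28 neuroectoderm and 38 Hox genes were past the adjusted p in limma, each of them higher. The Hox list stood at 4.82% ± 0.154, 6.89% ± 0.424 and 12.7% ± 0.484 on D0, D1 and D2. Relative to other genes both lists were low in camera, with an adjusted p = 3.3e-04 for Hox genes and 0.0086 for neuroectoderm with an estimated correlation (0.037 and 0.014 at the CpG-dense end of the genes). Among the lists, only formative and primed epiblast lost its camera call in this step, with adjusted p = 0.46 with an estimated correlation.

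Genes of the methylation machinery rose in 20 of 24 cases from D1 to D2 in TET_WT, although less than the median shift on average, so that the list was negative when centred. Dnmt1, the maintenance methyltransferase, rose by 24.7 ± 1.36 points and its partner Uhrf1 by 22.4 ± 1.09. The de novo genes Dnmt3a, Dnmt3b and Dnmt3l rose by 17.8 ± 0.899, 18.2 ± 1.05 and 16.6 ± 1.09, and Tet1, Tet2 and Tet3 by 22.1 ± 1.35, 23.5 ± 1.21 and 20.7 ± 0.953. Of the 2-cell-like genes 23 of 23 rose, with Pramel6 at 34.8 ± 2.07, and of the ubiquitously expressed genes 20 of 28 rose, with Gusb, a lysosomal enzyme, at 25.8 ± 1.14. Both lists were below the median shift when centred. For each list in this and every other contrast, the number of genes called when adjusted over the list alone equalled the number called over all 21434 genes. The window with the largest rise lay in Jdp2, a Jun dimerisation partner, at chromosome 12, 85619233 to 85622632, and went from 0.873% ± 0.590 on D0 and 8.44% ± 2.78 on D1 to 62.2% ± 5.15 on D2. On D2 it held 64.0% ± 0.703 in DNMT_WT and 71.5% ± 1.74 in TET_KO. A window in Mapt, which encodes tau, at chromosome 11, 104305028 to 104307648, rose from 14.1% to 66.7%, and windows in Tbx3os1, Llgl2, Ninl, Ak4 and Plekha7 rose by 50.2, 49.0, 49.0, 48.9 and 48.8 points.

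Between D0 and D1 the gains were smaller. Over all 21434 genes 2931 rose in TET_WT, 11921 in DNMT_WT and 617 in TET_KO. In TET_WT, Stat3, which transmits the LIF signal, rose by 12.9 ± 1.13 points, Pecam1 by 11.5 ± 1.13, Gata1 by 14.6 ± 1.36, Kit by 13.5 ± 1.23 and Pramel7 by 20.4 ± 1.84. The lists held 6 risen naive pluripotency genes of 30, 9 germline genes of 50, 4 haematopoietic regulators of 48, 4 imprinted loci of 36 and 5 2-cell-like genes of 23, and every list turned negative against the median shift of 8.46 points, the 2-cell-like list without passing the test. Mesoderm and endoderm, primitive endoderm and trophoblast, and methylation machinery each had 2 risen genes and ubiquitously expressed genes had 3. Formative, neuroectoderm and Hox genes had 0 called by limma at a minimum of 10 points (20, 16 and 19 past the adjusted p at any size), with Ncam1 at 9.44 ± 1.05, Tubb3 at 7.01 ± 1.36 and Hoxc4 at 5.78 ± 0.965 points. In DNMT_WT the D0 to D1 calls were 10 naive pluripotency genes, 7 formative, 32 germline, 17 imprinted, 21 haematopoietic, 1 neuroectoderm, 6 mesoderm and endoderm, 9 primitive endoderm and trophoblast, 0 Hox (39 past the adjusted p at any size), 16 machinery, 4 2-cell-like and 14 ubiquitously expressed. Of the 12 lists 11 were negative when centred on a median shift of 10.3 points, the machinery list without passing the test. Gata1 rose there by 22.4 ± 1.36, Etv6 by 19.8 ± 1.11 and Magea4 by 21.7 ± 2.71 points. In TET_KO, 1 germline gene, 1 mesoderm gene and 2 2-cell-like genes rose from D0 to D1: Tex101 by 10.3 ± 1.33, Msgn1 by 11.1 ± 1.82, Tdpoz4 by 10.5 ± 1.25 and Pramel6 by 10.3 ± 2.07 points, with all 12 lists below the median shift of 8.43 when centred. The other lists of TET_KO had 0 called by limma at 10 points in this step, and past the adjusted p at any size were 23 naive pluripotency, 25 formative, 34 imprinted, 45 haematopoietic, 17 neuroectoderm, 21 primitive endoderm and trophoblast, 30 Hox, 23 machinery and 22 ubiquitously expressed genes. Hox and neuroectoderm genes were again low against other genes, in TET_WT with adjusted p = 5.9e-04 and 0.0034 and in TET_KO with 0.0025 and 0.011, with an estimated correlation. At the CpG-dense end of the genes the calls ended for Hox genes in TET_WT (adjusted p = 0.15 with an estimated correlation) and for both lists in TET_KO (0.31 and 0.15), and neuroectoderm in TET_WT had 0.041. In TET_WT the calls of the naive, mesoderm and ubiquitously expressed lists ended at adjusted p = 0.58 with an estimated correlation and that of the formative list at 0.22. In DNMT_WT those of the Hox and neuroectoderm lists ended at adjusted p = 0.28 with an estimated correlation, those of the naive and formative lists at 0.92 and that of the 2-cell-like list at 0.90. In TET_KO the naive, formative, 2-cell-like and ubiquitously expressed lists ended at adjusted p = 0.38 with an estimated correlation and mesoderm and endoderm at 0.59.

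From D1 to D2, DNMT_WT gained most. Over all 21434 genes 20885 rose in DNMT_WT and 11175 in TET_KO. The genes named next are of DNMT_WT. Piwil1, a piRNA-binding protein of the testis, rose by 46.9 ± 1.20 points, Tcl1 by 44.2 ± 1.13, Erg by 45.7 ± 1.25, Col4a2 by 44.5 ± 1.07 and Pramel6 by 50.7 ± 2.07. Risen genes numbered 24 naive pluripotency, 21 formative, 50 germline, 36 imprinted, 44 haematopoietic, 24 mesoderm and endoderm, 21 primitive endoderm and trophoblast, 22 machinery, 23 2-cell-like and 21 ubiquitously expressed genes. Of the neuroectoderm genes 15 of 28 rose and of the Hox genes 18 of 39, and all 12 lists were negative after centring on a median shift of 40.5 points. In TET_KO the step raised 16 naive pluripotency, 5 formative, 27 germline, 13 imprinted, 19 haematopoietic, 0 neuroectoderm (28 at any size in limma), 8 mesoderm and endoderm, 11 primitive endoderm and trophoblast, 0 Hox (38 at any size), 9 machinery, 18 2-cell-like and 6 ubiquitously expressed genes, and 11 of the 12 lists were negative when centred on 12.8 points. The 2-cell-like list was no longer past the test there. Nanog rose by 21.4 ± 1.03, Tdh by 20.5 ± 1.08, Etv5 by 16.2 ± 1.19, Sycp2 of the meiotic chromosome axis by 17.9 ± 1.00 and the embryonic globin gene Hbb-y by 17.8 ± 1.73 points. A pair of adjoining windows in Esrrb, from 86476153 to 86483253 on chromosome 12, rose by 44.2 and 44.0 points in TET_KO. Hox and neuroectoderm genes ranked low against other genes in this step too, with adjusted p = 7.3e-05 and 0.0046 in DNMT_WT and 0.0012 and 0.0062 in TET_KO with an estimated correlation. At the CpG-dense end the Hox calls ended, with adjusted p = 0.074 and 0.069 with an estimated correlation, and neuroectoderm had 0.041 and 0.014. Ended calls were, in DNMT_WT, naive and ubiquitously expressed at adjusted p = 0.79 and formative at 0.24, and, in TET_KO, formative and mesoderm at 0.51, all with an estimated correlation.

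In the limma fit over windows, 122659 windows changed by at least 10 points from D0 to D1 in TET_WT (122629 higher, 30 lower) and 391085 from D1 to D2 (391075 higher, 10 lower). DNMT_WT had 217827 (217821 higher) and then 421755 (421751 higher), and TET_KO 89414 (89404 higher) and then 292265 (292246 higher). Relative to each library's median the counts and their split were different. Lower in this sense mostly means a rise smaller than that of the median, or no change, and not a loss. TET_WT then had 1314 higher and 976 lower windows in the first step and 9661 higher and 78921 lower in the second, DNMT_WT 40126 and 13270 followed by 11625 and 112625, and TET_KO 71 and 961 followed by 3301 and 21718. At a minimum of 20 points the first step in TET_WT kept a count of 466 windows and that in TET_KO 71. The p-values measure the spread between these libraries only, since the labels do not say whether replicates were separate cultures.

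**Figure D2:**
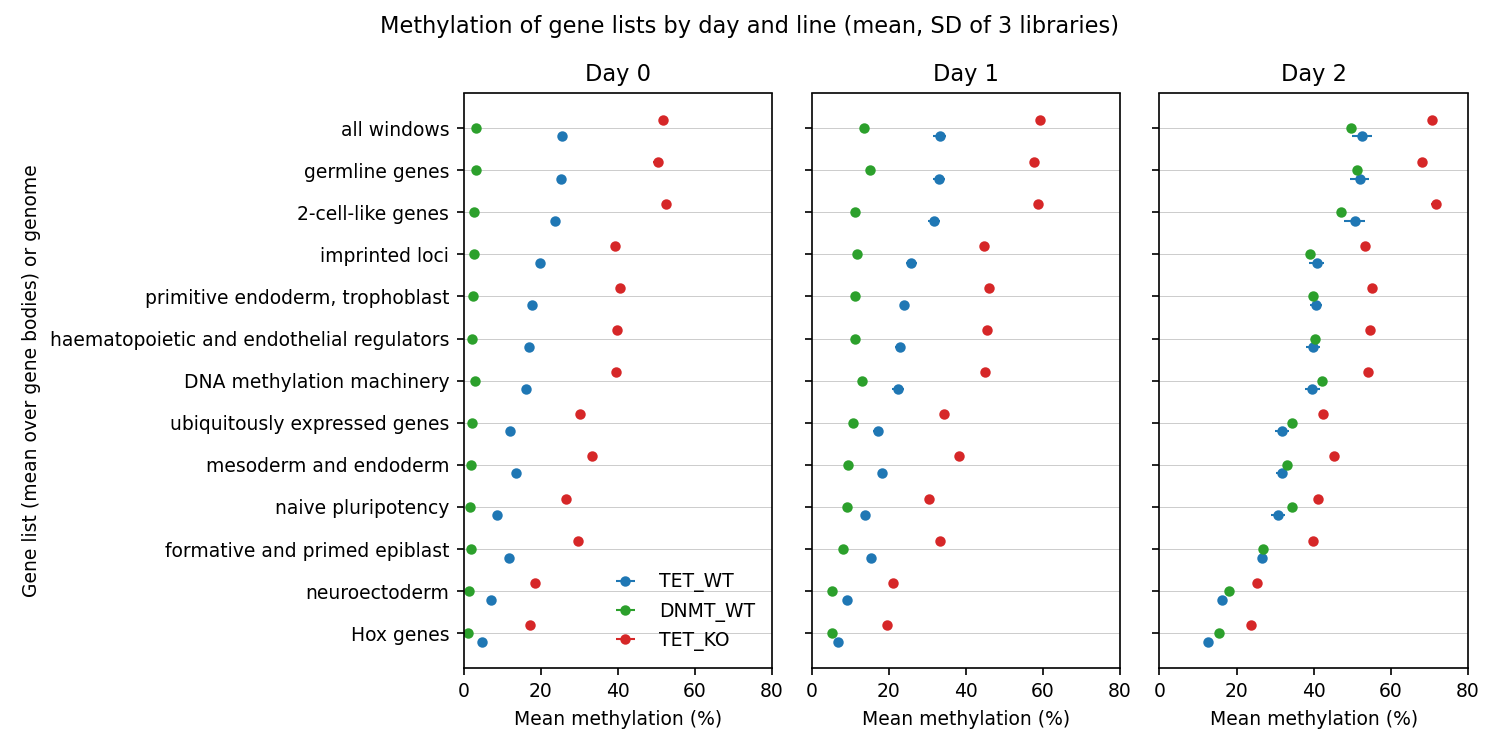
Mean methylation in percent (x axes) of 12 gene lists and of all windows (rows) on D0, D1 and D2 (panels), with a point and SD of 3 libraries for each line. On D2 the naive list stood at 30.7% in TET_WT, 34.4% in DNMT_WT and 41.3% in TET_KO and the Hox list at 12.7%, 15.4% and 23.8%; centred on library medians, both lists were instead lower in TET_KO than in TET_WT.

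The second comparison, TET_KO against TET_WT on the same day, asked how methylation differed in the Tet knockout before and during the exit from pluripotency. On D0 the knockout was more methylated in percent at 20618 of 21434 genes and less at 1. Tet1 stood at 48.9% ± 1.66 against 13.3% ± 0.488 in the parental line, Nanog at 24.8% ± 0.804 against 4.43% ± 0.834, and Pecam1 at 57.2% ± 0.792 against 18.7% ± 0.190. Genome means differed by 26.3 ± 0.674 points on D0, 26.0 ± 1.04 on D1 and 18.3 ± 1.64 on D2, with all 3 knockout libraries above all 3 parental libraries on each day (exact permutation p = 0.1, the smallest possible). With line labels permuted within days the mean difference was 23.5 points, with a two-sided exact permutation p of 0.00025, the smallest possible. Library medians moved further still, by 30.4, 30.3 and 20.7 points, so that a list mean was lower in TET_KO against this shift wherever its centred value is given as negative, while single genes above the shift of the day lay higher. The mean of all windows was itself -4.10 on D0 and -2.46 on D2 when centred. A small negative value, such as that of the 2-cell-like list on D0, therefore need not lie below the genome mean.

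Naive pluripotency genes rose in 20 of 30 cases on D0, the list mean being 17.8 ± 0.675 points higher in percent and -12.6 points when centred. At the CpG-dense end of the genes the list's median difference was 1.38 points. It was 20.7 over gene bodies, and 14.2 at the dense end of all genes. The formative list had 2.14 points at the dense end and 19.6 over gene bodies, and the germline list 23.2 and 25.4. Pecam1 rose by 38.6 ± 1.13, Jam2 by 33.6 ± 1.09, Tfcp2l1 by 33.4 ± 1.29 and Stat3 by 32.8 ± 1.13. Formative and primed epiblast genes rose in 24 of 31 cases (17.7 ± 0.548 points, centred -12.7), with the Wnt ligand gene Wnt8a at 33.7 ± 1.21, the Nodal antagonist gene Lefty2 at 28.0 ± 1.55 and Spry4, a feedback inhibitor of FGF signalling, at 27.8 ± 0.759. All 50 germline genes rose (25.4 ± 0.928, centred -4.997), among them Tuba3a at 33.5 ± 1.34 and the germ cell helicase gene Ddx4 at 32.7 ± 1.18. Of 36 imprinted loci 30 rose and 1 fell (19.6 ± 0.768, centred -10.8), with Ddc at 34.7 ± 1.09 and Sgce at 29.7 ± 1.08. The member that fell was Peg13, at 32.2% ± 2.34 in TET_KO and 42.9% ± 2.52 in TET_WT, named here after its value was seen. Haematopoietic and endothelial regulators rose in 43 of 48 cases (22.8 ± 0.673, centred -7.59), with Kit at 36.6 ± 1.23, Etv6 at 36.3 ± 1.11 and Gata1 at 35.4 ± 1.36.

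Lineage genes of other fates moved the same way. Neuroectoderm genes rose in 15 of 28 cases (11.4 ± 0.407, centred -18.99), with Pax3 at 26.5 ± 0.902 and Pax7 at 24.2 ± 0.978, both factors of neural tube and crest. Mesoderm and endoderm genes rose in 26 of 28 (19.9 ± 0.553, centred -10.5), with Tbx6 at 43.9 ± 2.63 and Msgn1 at 35.7 ± 1.82. Primitive endoderm and trophoblast genes rose in 22 of 24 (22.7 ± 0.633, centred -7.68), with Sparc at 31.3 ± 1.32 and Elf5, a trophoblast factor, at 29.7 ± 1.37. Hox genes rose in 22 of 39 (12.4 ± 0.362, centred -18.0), with Hoxd4 at 25.6 ± 1.38 and Hoxb1 at 23.9 ± 1.19. Machinery genes rose in 21 of 24 (23.2 ± 0.773, centred -7.16). Zbtb38, a reader of methylated DNA, rose by 38.0 ± 1.28, Dnmt1 by 36.5 ± 1.36, Uhrf1 by 31.1 ± 1.09, Dnmt3a by 25.0 ± 0.899, Dnmt3b by 20.8 ± 1.05 and Dnmt3l by 23.9 ± 1.09. Tet1, Tet2 and Tet3 rose by 35.5 ± 1.35, 29.0 ± 1.21 and 25.8 ± 0.953, which does not check the knockout itself. All 23 2-cell-like genes rose (29.0 ± 0.961, centred -1.37), led by Pramel7 at 47.6 ± 1.84, and 20 of 28 ubiquitously expressed genes rose (18.1 ± 0.692, centred -12.2), with Gusb at 35.3 ± 1.14 and the RNA polymerase gene Polr2a at 33.6 ± 1.24. The counts adjusted over the list alone were the same.

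On D1 the picture was close to that of D0, with 20 naive pluripotency, 24 formative, 50 germline, 31 imprinted, 44 haematopoietic, 14 neuroectoderm, 26 mesoderm and endoderm, 22 primitive endoderm and trophoblast, 24 Hox, 21 machinery, 23 2-cell-like and 20 ubiquitously expressed genes higher, 1 imprinted locus lower, and every list mean lower when centred. The lower locus was Peg13, named after its value was seen, at 38.0% ± 0.745 in TET_KO and 53.1% ± 2.43 in TET_WT. Spry4 differed by 31.96 ± 0.759 points, Dppa4 by 30.4 ± 0.882, Ddx4 by 33.9 ± 1.18, Ptprc, which encodes the leukocyte antigen CD45, by 31.8 ± 1.08 and Zscan4d by 37.4 ± 1.81. On D2 the differences were smaller for most genes, and 18387 of all 21434 genes were higher, against 20589 on D1. Naive pluripotency genes were higher in 16 and lower in 1 of 30 cases (10.5 ± 0.675, centred -10.2), with Dppa2 at 22.5 ± 1.35 and Nanog at 21.6 ± 1.03. At the CpG-dense end the list's median difference was 0.625 points, against 12.3 over gene bodies and 9.25 at the dense end of all genes. The lower gene was Tex19.1, named after its value was seen, which stood at 41.5% ± 1.44 in TET_KO and 53.1% ± 1.85 in TET_WT. Formative genes were higher in 20 of 31 (13.2 ± 0.548, centred -7.49), and Spry4 kept a difference of 31.2 ± 0.759. Germline genes were higher in 45 of 50 (16.2 ± 0.928, centred -4.54), with Ddx4 at 26.7 ± 1.18 and Asz1 at 24.2 ± 1.06. Imprinted loci were higher in 27 and lower in 1 of 36 (12.6 ± 0.768, centred -8.15), Snrpn at 23.0 ± 1.05 and Magel2 at 21.8 ± 1.86 being higher and Peg13 lower at -21.3 ± 1.68.

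Haematopoietic and endothelial regulators were higher on D2 in 38 of 48 cases (14.7 ± 0.673, centred -6.03). Ptprc stood at 74.2% ± 1.23 in TET_KO and 47.8% ± 2.79 in TET_WT, and the embryonic globin genes Hba-x, Hbb-y and Hbb-bh1 differed by 25.5 ± 1.75, 25.3 ± 1.73 and 24.9 ± 2.02 points. Neuroectoderm genes were higher in 10 of 28 (9.09 ± 0.407, centred -11.6), with Pax3 at 20.9 ± 0.902, mesoderm and endoderm genes in 19 of 28 (13.6 ± 0.553, centred -7.13), with Gata4 at 18.8 ± 0.816, and primitive endoderm and trophoblast genes in 20 of 24 (14.5 ± 0.633, centred -6.24), with the placental genes Tpbpa at 29.6 ± 1.63 and Prl3d1 at 26.7 ± 1.67. Hox genes were higher in 19 of 39 (11.2 ± 0.362, centred -9.57), with Hoxb1 at 24.1 ± 1.19. Machinery genes were higher in 18 of 24 (14.4 ± 0.773, centred -6.33), with Tet1 at 26.7 ± 1.35, Tet2 at 17.4 ± 1.21, Tet3 at 13.4 ± 0.953, Dnmt1 at 18.6 ± 1.36 and Uhrf1 at 16.1 ± 1.09. Ubiquitously expressed genes were higher in 17 of 28 (10.6 ± 0.692, centred -10.1). Of the 2-cell-like genes 22 of 23 were higher (21.0 ± 0.961, centred 0.273 and no longer past the test), with Usp17ld at 30.5 ± 1.74. Counts adjusted over the list alone were again the same.

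Against other genes, camera with its preset correlation placed several lists below the general rise in TET_KO, and no list held this with an estimated correlation. On D0 the naive list had adjusted p = 5.0e-09 and then adjusted p = 0.21 with an estimated correlation, neuroectoderm 1.3e-06 and then 0.12, Hox genes 1.2e-04 and then 0.12, ubiquitously expressed genes 0.0017 and then 0.74, and imprinted and formative genes 0.012 and 0.039 and then 0.89 each. On D1 the calls of the naive, neuroectoderm and Hox lists ended at adjusted p = 0.18 with an estimated correlation, imprinted loci at 0.87 and ubiquitously expressed genes at 0.73. On D2 the naive list had 4.8e-09 and then 0.62, ubiquitously expressed genes 0.015 and imprinted loci 0.047, and then 0.99 each with an estimated correlation.

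The windows with the largest differences lay further apart than gene means. In Lhx9, a LIM homeobox gene, the window at chromosome 1, 138841661 to 138842298 held 73.8% ± 7.43 in TET_KO on D0 against 0.0597% ± 0.103 in TET_WT and 0.158% ± 0.273 in DNMT_WT, and on D2 87.5% ± 1.05 against 2.56% ± 3.86 and 1.15% ± 0.714. The adjoining window at chromosome 1, 138840133 to 138841660 differed by 78.0 ± 1.69, 83.7 ± 1.69 and 79.5 ± 1.69 points on D0, D1 and D2. Windows in Nrros, Fat1 and Epb41l4a were higher by 69.9 ± 5.24, 67.1 ± 2.50 and 67.1 ± 2.05 points on D0, and an intergenic pair on chromosome 11, from 98066172 to 98069508, by 68.9 and 68.0 points. A few windows went the other way. The window at chromosome 15, 72809399 to 72810122, in Trappc9 and at the imprinted Peg13, held 7.04% ± 3.58 in TET_KO and 44.2% ± 3.23 in TET_WT on D0, and 5.67% ± 1.85 and 60.0% ± 5.75 on D2. In Mtmr7, a myotubularin-related gene, the window at chromosome 8, 40567071 to 40571237 held 19.99% ± 1.57 against 76.4% ± 0.947 on D2, and a window in Tex21 at chromosome 12, 76222915 to 76228203 16.4% ± 2.02 against 67.3% ± 4.34. These windows were also low in DNMT_WT on D2, at 10.7%, 14.2% and 11.6%. A window at chromosome 9, 123924847 to 123925519 stayed below 1% in TET_KO on each day and rose from 19.4% to 43.5% in TET_WT, and a window in Erc2 differed by -41.0 ± 3.62 points on D0.

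**Figure D3:**
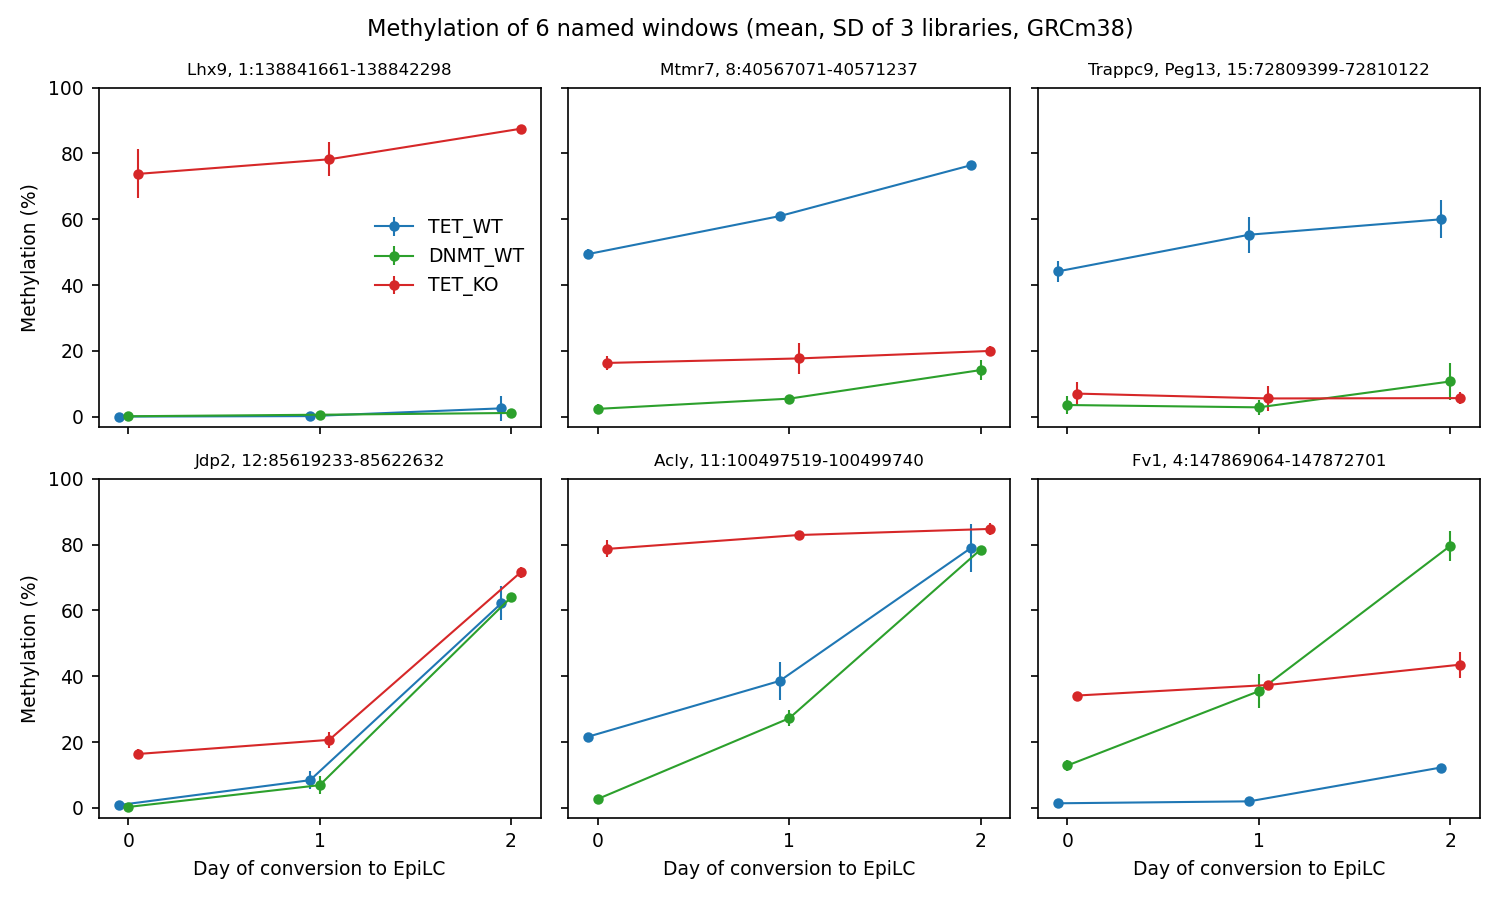
Methylation in percent (y axis) of 6 windows against day of conversion (x axis), with the mean and SD of 3 libraries for each line. Lhx9 was high only in TET_KO of these lines, the Mtmr7 and Peg13 windows were high only in TET_WT, Jdp2 rose to 62.2%, 64.0% and 71.5% on D2 in TET_WT, DNMT_WT and TET_KO, Acly started at 78.7% in TET_KO, and Fv1 reached 79.6% in DNMT_WT.

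Over the genome 412638 windows differed between TET_KO and TET_WT on D0 (412539 higher, 99 lower), 411559 on D1 (411449 and 110) and 374554 on D2 (374313 and 241). Centred on library medians the split turned, to 16376 higher and 85414 lower on D0, 12255 and 88161 on D1 and 37633 and 79909 on D2. Lower in this sense mostly means a rise smaller than the median shift, or no change. It is not a loss, as only 99, 110 and 241 windows were lower in percent. The windows higher on all 3 days numbered 370677, against 321930 expected of independent lists, and those lower on all 3 days 54. Lower windows shared by D0 and D1 numbered 60, where 0.0245 were expected. Of the lower windows, 98 of 99 on D0 were also lower in DNMT_WT than in TET_WT (88.0 expected of independent lists), 106 of 110 on D1 (94.1 expected) and 154 of 241 on D2 (25.3 expected). Both comparisons use the same TET_WT libraries, which these expected numbers leave out. They also count windows under 10% in TET_WT, which could not fall by 10 points. Of the autosomal windows that could, 98.4% were lower in DNMT_WT on D0, 92.0% on D1 and 10.4% on D2. The overlap on D0 and D1 is thus near that of any such window, and only that on D2 lies far above it. In a simulation with no effect, all lines, TET_WT included, were drawn anew around the TET_WT mean of the day. It gave 0, 0 and 0 windows lower in both on D0, D1 and D2. With no effect hardly any window can be called, so these numbers do not measure what the shared libraries add. The TET_WT libraries were not split between the comparisons. Part of any excess can come from them, and how much was not measured. Only 1 Tet knockout line was analysed here, so an effect of the clone cannot be separated from that of the genotype.

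The knockout difference depended on the class of window. Windows are named as holding a set number of CpGs, so that short windows are the CpG-dense ones. Windows under 3 kb stood at 18.2% ± 0.245 in TET_WT and 37.8% ± 0.763 in TET_KO on D0, a difference of 19.5 ± 0.652 points that turned to -10.8 when centred. On D2 they differed by 11.5 ± 0.652 points (centred -9.28). Windows of 3 to 8 kb differed by 28.4 ± 0.975 on D0 and 17.6 ± 0.975 on D2 (centred -2.02 and -3.11). Windows of 8 to 16 kb kept their difference, with 25.6 ± 1.03 and 25.6 ± 1.03 (centred -4.76 and 4.87), and windows over 16 kb went from 21.3 ± 0.998 to 26.3 ± 0.998 (centred -9.04 and 5.55). Autosomes differed by 26.4 ± 0.927 and 18.1 ± 0.927 points (centred -3.93 and -2.59). The X chromosome differed by 24.7 ± 0.943 and 20.8 ± 0.943 points (centred -5.67, and 0.0877 on D2, no longer past the test), and the Y chromosome by 15.1 ± 0.954 and 19.9 ± 0.954 (centred -15.3 and -0.797). Gene bodies differed by 26.4 ± 0.904 and 16.7 ± 0.904 points (centred -3.93 and -4.01), and the rest of the genome by 26.0 ± 0.964 and 20.5 ± 0.964 (centred -4.35 and -0.191, the latter no longer past the test). Among windows under 3 kb 64.4% were called higher in TET_KO on D0, against 98.6% of other windows (odds ratio 0.0259).

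**Figure D4:**
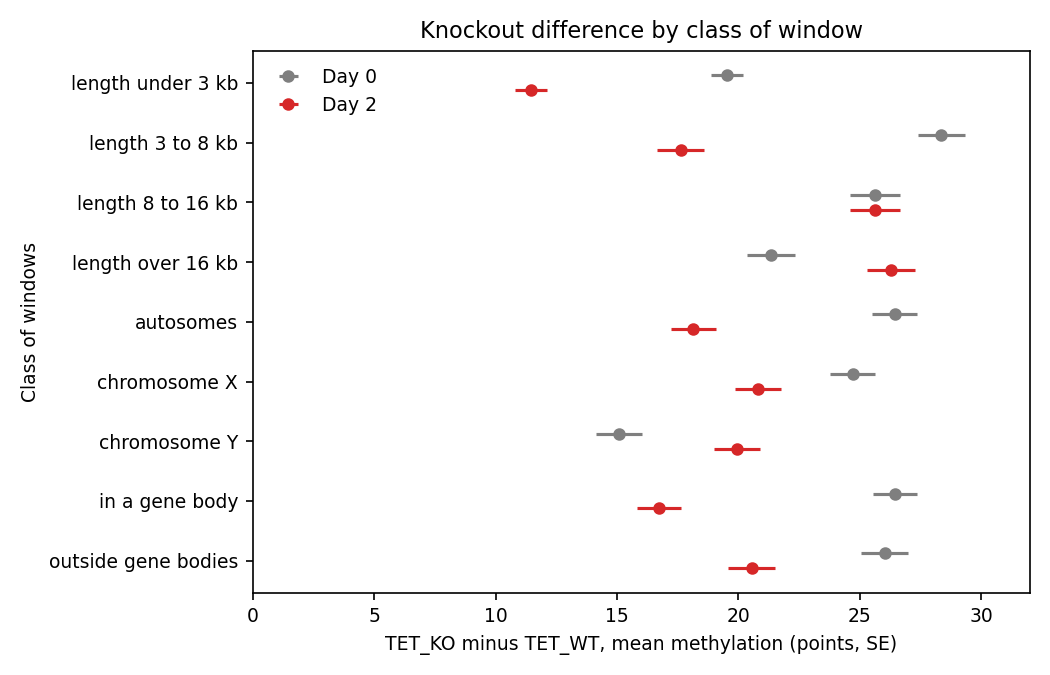
Difference in mean methylation, TET_KO minus TET_WT, in points (x axis, SE bars from limma) for classes of windows (y axis) on D0 and D2. The difference fell from 28.4 to 17.6 points in windows of 3 to 8 kb and went from 21.3 to 26.3 in windows over 16 kb; centred on library medians these became -2.02 and -3.11, and -9.04 and 5.55.

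The third comparison tested whether the D0 to D2 gain itself differed between TET_KO and TET_WT. The genome gained 27.1 ± 1.51 points in TET_WT and 19.04 ± 0.929 in TET_KO, and the gain over all windows differed by -8.01 ± 1.31 points (limma adjusted p = 4.4e-06), which became 1.63 when centred on a median shift of -9.64. The SE of 1.31 pools all 9 groups and is smaller than the 1.51 of the TET_WT gain alone, so it understates the spread. Kit gained from 21.7% ± 1.19 to 61.4% ± 2.86 in TET_WT and from 58.3% ± 1.05 to 75.8% ± 0.876 in TET_KO, a difference of -22.2 ± 1.74 points. Pramel7 differed by -31.9 ± 2.61, Tbx6 by -21.3 ± 3.72, Nr5a2, a nuclear receptor of the naive network, by -19.9 ± 1.42, Polr2a by -18.4 ± 1.75 and Dnmt1 by -17.9 ± 1.92. Smaller gains in TET_KO were called for 10 naive pluripotency, 5 formative, 24 germline, 13 imprinted, 19 haematopoietic, 1 neuroectoderm, 7 mesoderm and endoderm, 11 primitive endoderm and trophoblast, 11 machinery, 7 2-cell-like and 12 ubiquitously expressed genes, the same numbers when adjusted over the list alone, and the sign of every list mean turned positive when centred. The germline (0.456), primitive endoderm and trophoblast (1.44) and machinery (0.830) means were not past the test when centred (adjusted p = 0.096, 0.076 and 0.11). These means lay below the 1.63 of all windows. Over all 21434 genes a smaller gain was called in 9928 and a larger gain in 269. Of the Hox genes 0 of 39 were called, and limma gave 9 lower and 1 higher at an adjusted p under 0.05 without a minimum size. Hoxc4 differed by -7.86 ± 1.37 and Hoxa9 by -5.96 ± 0.919 points. Against other genes the Hox list ranked high in this contrast with adjusted p = 0.037 with an estimated correlation, a call that ended at the CpG-dense end of the genes (adjusted p = 0.41 with an estimated correlation), and neuroectoderm lost its call with adjusted p = 0.37 with an estimated correlation.

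By class of window, the gain in TET_KO less that in TET_WT was -10.7 ± 1.38 points in windows of 3 to 8 kb (centred -1.09), was level in windows of 8 to 16 kb at -0.00459 ± 1.46 (centred 9.64), and exceeded that of TET_WT in windows over 16 kb by 4.95 ± 1.41 and on the Y chromosome by 4.85 ± 1.35 (centred 14.6 and 14.5). Of the 2143 windows over 16 kb, 709 lay on the Y chromosome, so these results share windows. The SEs pool the spread of all 9 groups. TET_WT on D2 varied more than that, with SD 3.08 over 16 kb and 2.86 on the Y chromosome. The SEs and limma p-values thus understate the spread in this contrast. On the autosomes alone the gain in windows over 16 kb was larger in TET_KO by 3.59 points. There the direction turned when windows of the same D0 level were compared, in a test run after the result was known. Over 3 bins of 10 points TET_WT gained 23.1 and TET_KO 19.9 points, a difference of -3.27 ± 2.12, within 2 SE of 0. The value for 8 to 16 kb changed sign without TET_WT D0 replicate 1 (0.228), TET_WT D2 replicate 2 (1.80), TET_KO D0 replicate 3 (0.660) or TET_KO D2 replicate 3 (0.763). Called windows numbered 207449, 11099 with a larger and 196350 with a smaller gain in TET_KO. Centred, 79330 were larger and 37536 smaller, and without TET_WT D2 replicate 2 19060 were larger. With the p-value taken on the logit scale, and direction and minimum kept in percent, 675 were larger and 119815 smaller. By the logit difference itself, 902 were larger and 148203 smaller past the adjusted p at any size. A smaller gain was called in 56.0% of windows of 3 to 8 kb and 13.7% of windows of 8 to 16 kb, and a larger gain in 18.96% of windows on the Y chromosome against 2.37% elsewhere. The window with the largest shortfall lay in Acly, the ATP citrate lyase gene, at chromosome 11, 100497519 to 100499740. It went from 21.7% ± 0.601 to 79.0% ± 7.22 in TET_WT and from 78.7% ± 2.58 to 84.7% ± 1.89 in TET_KO.

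**Figure D5:**
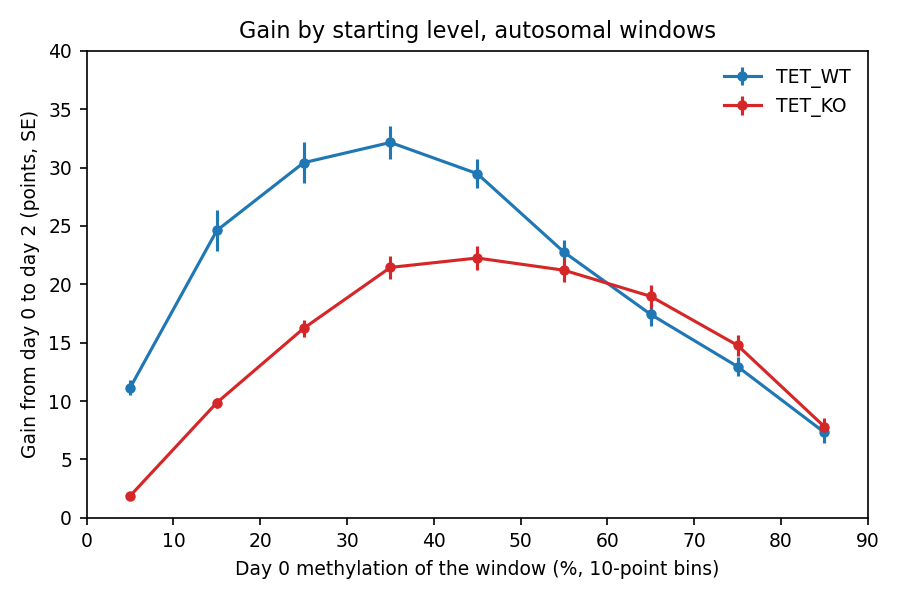
Gain in methylation from D0 to D2 in points (y axis, SE of 3 libraries a day) against the D0 level of autosomal windows in bins of 10 points (x axis) for TET_WT and TET_KO. In the bin from 20 to 30% the gain was 30.4 points in TET_WT and 16.2 in TET_KO, and in the bin from 60 to 70% 17.4 and 18.97.

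The last comparison set the wild-type lines against each other, to show how far lines differ with no Tet knockout. On D0 DNMT_WT was far less methylated than TET_WT, with 1.62% ± 0.124 against 8.73% ± 0.188 over the naive list, 2.14% ± 0.0698 against 16.9% ± 0.257 over haematopoietic regulators and 3.24% ± 0.0926 against 25.1% ± 0.451 over germline genes. Genome means differed by -22.3 ± 0.227 points on D0, -19.6 ± 0.987 on D1 and -2.94 ± 1.52 on D2, with an exact permutation p of 0.1 on each day, the smallest possible. Over the days together the mean was -15.0 points, with a two-sided exact permutation p of 0.00025, the smallest possible. The D2 difference became -1.48 points without TET_WT D2 replicate 2. Over all 21434 genes 18177 were lower in DNMT_WT on D0 and 15887 on D1. On D0 Peg13 was lower by a difference of -38.9 ± 1.68 points, Magea4 by -37.6 ± 2.71, Igf2r by -30.1 ± 0.974, Cdh2 by -29.7 ± 1.12 and Kdr, a receptor of vascular growth factor, by -29.4 ± 1.14. Lower on D0 were 9 naive pluripotency, 10 formative, 50 germline, 28 imprinted, 31 haematopoietic, 6 neuroectoderm, 14 mesoderm and endoderm, 17 primitive endoderm and trophoblast, 1 Hox, 17 machinery, 21 2-cell-like and 15 ubiquitously expressed genes, and all 12 lists were higher instead when centred on a median shift of -22.9 points. On D1 the numbers were 6, 7, 46, 25, 28, 2, 11, 14, 0, 13, 21 and 7 in the same order, again with all lists higher when centred (2-cell-like without passing the test) on -21.0, and 16 Hox genes passed the adjusted p at any size in limma.

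By D2 the wild-type lines had nearly met. Over all 21434 genes 133 were higher and 671 lower in DNMT_WT. Klf5 and Mybl2 of the naive list were higher in DNMT_WT by 10.5 ± 1.06 and 10.1 ± 0.943 points, Sox3 of the formative list by 12.2 ± 0.619, and Zfp57, which protects imprints, and Tet1 of the machinery list by 12.3 ± 0.925 and 10.6 ± 1.35. Lower were Peg13 and Mest of the imprinted list at -29.2 ± 1.68 and -15.2 ± 1.62, Rhox5 and Asz1 of the germline list at -16.2 ± 2.05 and -10.4 ± 1.06, Prl3d1 at -14.1 ± 1.67, and Zscan4e and Usp17lb of the 2-cell-like list at -11.1 ± 1.94 and -10.9 ± 2.16. No haematopoietic, neuroectoderm, mesoderm and endoderm, Hox or ubiquitously expressed gene was called by limma at 10 points, although 14, 20, 16, 30 and 16 of them passed the adjusted p alone. Of the lists, 8 had a higher mean in DNMT_WT and 4 a lower one, and 11 were higher when centred on -2.97. Before centring the formative, germline, haematopoietic, and primitive endoderm and trophoblast means were not past the test, and after it the 2-cell-like mean was not. Hox genes ranked high against other genes on each day, with adjusted p = 4.0e-05, 3.4e-06 and 0.014 with an estimated correlation, and the naive and neuroectoderm lists on D0 (0.034 and 0.0090) and D1 (0.034 and 0.0041). At the CpG-dense end the calls of the naive list ended on D0 and D1, with adjusted p = 0.078 and 0.095 with an estimated correlation, while Hox genes had 0.0080, 9.5e-04 and 0.0062 and neuroectoderm 0.0080 and 0.0037. Ended calls on D0 were formative, mesoderm, machinery and ubiquitously expressed genes, with adjusted p = 0.22, 0.57, 0.77 and 0.18 with an estimated correlation. On D1 they were the same lists at 0.19, 0.37, 0.60 and 0.14 and germline genes at 0.79. On D2 the naive, neuroectoderm, mesoderm, machinery and ubiquitously expressed lists ended at 0.33, 0.23, 0.61, 0.64 and 0.43. In Fv1, a retroviral restriction gene, the window at chromosome 4, 147869064 to 147872701 held 79.6% ± 4.67 in DNMT_WT and 12.3% ± 1.23 in TET_WT on D2, and windows in Msi2 and Togaram1 were higher by 56.0 ± 2.14 and 55.8 ± 2.14 points. The Mtmr7 window was lower at -62.2 ± 1.89 and a window in Cadps at -54.7 ± 2.96.

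In windows, 394736 differed on D0 (4 higher, 394732 lower in DNMT_WT), 380169 on D1 (56 and 380113) and 54466 on D2 (7915 and 46551, or 12372 and 30369 without TET_WT D2 replicate 2). When centred the split was 70019 higher and 60085 lower on D0, 71201 and 35338 on D1 and 18390 and 21154 on D2. On D0 and D1 higher in this sense mostly means a shortfall smaller than that of the median, or no change. The D0 to D2 gain differed between these lines in 367458 windows (367371 larger and 87 smaller in DNMT_WT), or 55597 larger and 74445 smaller when centred. Smaller when centred mostly means an excess under the median shift, as only 87 were smaller in percent. Over all 21434 genes 18277 had a larger gain in DNMT_WT. Larger gains were called for 16 naive pluripotency, 13 formative, 48 germline, 28 imprinted, 35 haematopoietic, 7 neuroectoderm, 16 mesoderm and endoderm, 15 primitive endoderm and trophoblast, 6 Hox, 20 machinery, 22 2-cell-like and 17 ubiquitously expressed genes, and 11 of the 12 lists turned negative when centred on 19.9 points. For this difference of gains the Hox list ranked low, with adjusted p = 0.023 with an estimated correlation, which ended at the CpG-dense end (adjusted p = 0.43 with an estimated correlation), and calls ended for the naive and formative lists at 0.61, neuroectoderm at 0.19 and ubiquitously expressed genes at 0.74. The lines come from different parents, and the labels give neither strain nor passage.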

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

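The tests on mitochondrial windows, on missing Y windows, and on bins weighted by windows or parted at 50% were chosen after the results they bear on had been seen. The test of the starting level with bins counted alike and those of chromosome Y were written before their own values were seen, though after the differences by length and chromosome were known. Each result listed next stands here because the D0 to D2 gain differed between lines in a test of that difference itself.

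TET_KO and TET_WT differed in gain in 207449 windows, and DNMT_WT and TET_WT in 367458. Over all windows the gain of TET_KO less that of TET_WT was -8.01 points (centred 1.63) and that of DNMT_WT less that of TET_WT 19.3. By class the TET_KO difference was -8.08 points under 3 kb (centred 1.56), -10.7 from 3 to 8 kb (-1.09), 4.95 over 16 kb (14.6), -8.30 on autosomes (1.34), -3.88 on the X chromosome (5.76), 4.85 on the Y chromosome (14.5), -9.73 in gene bodies (-0.0860, not past the test) and -5.49 outside them (4.16). By list it was -7.25 points for naive pluripotency, -4.45 formative and primed epiblast, -9.19 germline, -6.97 imprinted, -8.09 haematopoietic and endothelial, -2.30 neuroectoderm, -6.31 mesoderm and endoderm, -8.20 primitive endoderm and trophoblast, -1.22 Hox, -8.81 machinery, -8.00 2-cell-like and -7.52 ubiquitously expressed genes, and every list turned positive when centred, germline, primitive endoderm and trophoblast, and machinery without passing the test. The Hox value missed the adjusted threshold without TET_WT D0 replicate 1 (-1.14), TET_WT D2 replicate 2 (-0.953), TET_KO D0 replicate 3 (-1.01) or TET_KO D2 replicate 3 (-1.08).

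Genes with a smaller gain in TET_KO were Pramel7 (-31.9 points), Kit (-22.2), Tbx6 (-21.3), Nr5a2 (-19.9), Polr2a (-18.4), Dpep3 (-18.0), Dnmt1 (-17.9), the laminin gene Lama1 (-17.2), Sgce (-16.5), Lef1 (-13.9) and Tubb3 (-11.2). Windows with the largest called differences were chromosome 16, 45566294 to 45571078, in Slc9c1 (31.9), chromosome Y, 75113094 to 75117398 (30.5), the Acly window on chromosome 11 (-51.2) and chromosome 2, 87517379 to 87522101 (-49.3).

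The smaller gain in TET_KO was weighed against its higher starting level, which leaves less to gain. Windows of the same D0 level were compared in 9 bins of 10 points, with at least 20 autosomal windows in each line. With each bin counted alike, the difference of gain averaged -5.98 points (SE 1.38). From the lowest bin up it was -9.25, -14.7, -14.2, -10.7, -7.23, -1.55, 1.55, 1.82 and 0.490 points. The mean lay more than 2 SE past the bound of -2 points set beforehand. The lines fill the low bins unequally, however, with 410698 TET_WT and 143245 TET_KO windows under 50%. Windows still low in TET_KO are thus a selected part, and the mean does not decide whether the starting level is the whole cause. Weighted by TET_KO windows the mean was -9.28 (SE 1.503) under 50%, where 33.9% of these windows began, also past the bound, but -3.04 (SE 1.42) over all bins, within 2 SE of the bound, and 0.167 (SE 1.39) from 50% up, so that for windows starting there the starting level cannot be told apart from other causes. A bin holds different windows in each line, and within length classes from the shortest up the unweighted means, the last opposite in sign to the plain difference of that class, were -8.54 (SE 1.29), -7.55 (SE 1.52), -3.20 (SE 1.82) and -3.27 (SE 2.12). In the mitochondrial windows, which are almost unmethylated, the gains differed by -0.0223 points. This argues against unequal failure to convert unmethylated cytosine, while unequal conversion of methylated cytosine cannot be seen there. The knockout stays a candidate explanation that the single clone cannot separate from a clone effect.

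The gain on the Y chromosome was larger in TET_KO while that on the autosomes was smaller. From D0 to D2 the Y chromosome rose from 26.1% to 38.9% in TET_WT and from 41.2% to 58.8% in TET_KO. Autosomes rose from 25.4% to 52.7% and from 51.8% to 70.8%. In DNMT_WT the Y chromosome rose from 3.19% to 30.7% and the autosomes from 3.17% to 49.9%. More Y windows were missing in TET_WT (22.3% on D0, 22.5% on D2) than in TET_KO (11.9% and 12.7%). Y windows are longer, and matching on length brought the difference between the Y chromosome and the autosomes from 13.1 (SE 0.425) to 7.42 points (SE 0.275), which argues against length as the whole cause and leaves it as a part. A further test took the 1783 Y windows with no missing value in the 5 windows on either side, without subtracting the autosomes. There the gain of TET_KO less that of TET_WT was 4.53 points (SE 1.98), against 4.85 over all Y windows. The 4.53 points lay above the bound of 2 points by less than 2 SE. Thin coverage and repeats therefore cannot be told apart from a difference between the lines. Within length classes from the shortest up, Y windows had -2.04, 2.39, 6.10 and 6.48 points, and autosomes -8.17, -10.9, -0.0496 and 3.59.

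DNMT_WT was far below TET_WT on D0 although neither carries a Tet knockout. The mitochondrial windows, almost unmethylated in both lines, were higher in DNMT_WT by 0.110 points, against a nuclear difference of -22.3. This argues against unequal failure to convert unmethylated cytosine. Unequal conversion of methylated cytosine cannot be seen in such windows and stays open. A line with 2 X chromosomes and no Y could be low in methylation, and at most 18.1% of Y windows were missing in any DNMT_WT library, which argues against a line without a Y chromosome. Strain, passage and time in 2i are not given and stay open, as untested.

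For each contrast of 3 against 3 libraries the real split was the only 1 of 10 splits with as many windows, and 10 splits are too few for a share under 0.05. The counts were TET_WT D0 to D1 (122659 windows, highest other 17), TET_WT D1 to D2 (391085 windows, highest other 2), DNMT_WT D0 to D1 (217827 windows, highest other 0), DNMT_WT D1 to D2 (421755 windows, highest other 1), TET_KO D0 to D1 (89414 windows, highest other 10), TET_KO D1 to D2 (292265 windows, highest other 2), TET_KO against TET_WT on D0 (412638 windows, highest other 1), on D1 (411559 windows, highest other 0), on D2 (374554 windows, highest other 22), DNMT_WT against TET_WT on D0 (394736 windows, highest other 0), on D1 (380169 windows, highest other 0) and on D2 (54466 windows, highest other 546). For the differences of gain, 1 of 100 splits gave as many windows, the real split, in TET_KO (207449, highest other 160072) and in DNMT_WT (367458, highest other 346910). That share lies under 0.05 and argues against chance among these libraries. It does not exclude chance, as other splits also reached large counts.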

How the results depend on the processing

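The dense end of the gene was chosen as an alternative after the gene table was seen. After first results were seen, alternatives for class and list means were limited to TET_KO against TET_WT on D0 and D2 and to the difference of their gains, and dense-end values of single genes to counts. Alternatives that need the transcription start were not run. Every total of called windows stayed within 1.5 times with only the libraries of the contrast fitted, without the variance trend, with windows valued in at least 2 of 3 libraries, on autosomes alone, without windows over 50 kb and with a replicate block. With that block, which the absence of pairing does not call for, totals in the order of the contrasts in the next paragraph were 122665, 391098, 217831, 421756, 89420, 292270, 412649, 411558, 374558, 207463, 394741, 380172, 54482 and 367494. With the wild-type lines together as reference TET_KO differed in 420976, 420221 and 390735 windows on D0, D1 and D2, of which 6, 12 and 134 were lower. Depth limits all counts in an unknown way, as no coverage was given.

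Leaving out each library gave ranges of 104824 to 167738 (TET_WT D0 to D1), 373053 to 396931 (TET_WT D1 to D2), 214464 to 219432 (DNMT_WT D0 to D1), 421563 to 421796 (DNMT_WT D1 to D2), 76220 to 132697 (TET_KO D0 to D1), 270791 to 313580 (TET_KO D1 to D2), 411352 to 412988 (TET_KO against TET_WT on D0), 409634 to 412100 (TET_KO against TET_WT on D1), 359033 to 386589 (TET_KO against TET_WT on D2), 188213 to 223269 (the difference of gains of TET_KO), 393789 to 394900 (DNMT_WT against TET_WT on D0), 376224 to 385119 (DNMT_WT against TET_WT on D1), 42741 to 70288 (DNMT_WT against TET_WT on D2) and 352678 to 385616 (the difference of gains of DNMT_WT). Genome means ranged from -3.95 to -1.48 points for DNMT_WT against TET_WT on D2 and from 17.3 to 19.7 for TET_KO against TET_WT on D2, with 180 of 180 leave-one-out values on the same side. With medians over windows 12 of 20 genome means moved by more than the spread between replicates, all of them away from 0, among them TET_KO against TET_WT on D2, to 20.7 points, and with autosomes alone 1 did, DNMT_WT D0 to D2, to 46.7; none changed sign, and means pooled over lines or days, judged by permutation p instead, kept their side. The 8 to 16 kb difference of gains, -0.00459 with all libraries, ranged from -1.09 to 1.80, with 0.228 without TET_WT D0 replicate 1, 1.80 without TET_WT D2 replicate 2, 0.660 without TET_KO D0 replicate 3 and 0.763 without TET_KO D2 replicate 3, and was 1.11 with medians of windows. The Hox difference of gains missed the threshold with medians at -1.11. Of 528 class and list values 4 reversed and 4 weakened with a library left out, of 3330 gene values 2 weakened and of 1224 window values 30 weakened. Of 288 window counts 35 moved by over 1.5 times with a library left out, all of them counts of 1 direction and none a total; beyond counts under 100 these were 12372 higher in DNMT_WT on D2 without TET_WT D2 replicate 2, 30369 lower in DNMT_WT on D2 without TET_WT D2 replicate 2, 19060 with a larger gain in TET_KO without TET_WT D2 replicate 2 and 133 with a smaller gain in DNMT_WT without TET_WT D2 replicate 3. The cause was not tested.

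A minimum of 20 points, which by construction calls fewer windows, gave 466 (TET_WT D0 to D1), 231321 (TET_WT D1 to D2), 43811 (DNMT_WT D0 to D1), 71 (TET_KO D0 to D1), 12721 (TET_KO D1 to D2), 179991 (TET_KO against TET_WT on D2), 34657 (the difference of gains of TET_KO), 235075 (DNMT_WT against TET_WT on D1), 4362 (DNMT_WT against TET_WT on D2) and 218278 (the difference of gains of DNMT_WT). With no minimum there were 358973 (TET_WT D0 to D1), 370348 (TET_KO D0 to D1) and 174138 (DNMT_WT against TET_WT on D2). Totals for the logit scale took only its p-value, with direction and minimum kept in percent. The total that moved by over 1.5 times was that of the difference of gains of TET_KO, to 120490. By the logit difference itself the sign turned for the difference of gains of DNMT_WT in the windows of chromosome 12 at 76228217 (0.36 on the log2 scale), chromosome 11 at 19409238 (0.86), chromosome 15 at 49662424 (0.81) and chromosome 1 at 23301567 (1.02). The cause was not tested.

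Centring, which by construction removes the shift of the library median, left 2290 (TET_WT D0 to D1), 88582 (TET_WT D1 to D2), 53396 (DNMT_WT D0 to D1), 124250 (DNMT_WT D1 to D2), 1032 (TET_KO D0 to D1), 25019 (TET_KO D1 to D2), 101790 (TET_KO against TET_WT on D0), 100416 (TET_KO against TET_WT on D1), 117542 (TET_KO against TET_WT on D2), 116866 (the difference of gains of TET_KO), 130104 (DNMT_WT against TET_WT on D0), 106539 (DNMT_WT against TET_WT on D1) and 130042 (the difference of gains of DNMT_WT) windows. It turned or weakened class and list means as follows, in points. For TET_KO against TET_WT on D0: all windows -4.10, under 3 kb -10.8, 3 to 8 kb -2.02, 8 to 16 kb -4.76, over 16 kb -9.04, autosomes -3.93, X -5.67, Y -15.3, gene bodies -3.93, outside -4.35, naive -12.6, formative -12.7, germline -4.997, imprinted -10.8, haematopoietic -7.59, neuroectoderm -18.99, mesoderm and endoderm -10.5, primitive endoderm and trophoblast -7.68, Hox -18.0, machinery -7.16, 2-cell-like -1.37 and ubiquitously expressed -12.2. On D2: all windows -2.46, under 3 kb -9.28, 3 to 8 kb -3.11, autosomes -2.59, X 0.0877, Y -0.797, gene bodies -4.01, outside -0.191, naive -10.2, formative -7.49, germline -4.54, imprinted -8.15, haematopoietic -6.03, neuroectoderm -11.6, mesoderm and endoderm -7.13, primitive endoderm and trophoblast -6.24, Hox -9.57, machinery -6.33, 2-cell-like 0.273 and ubiquitously expressed -10.1. For the difference of gains: all windows 1.63, under 3 kb 1.56, 8 to 16 kb 9.64, autosomes 1.34, X 5.76, gene bodies -0.0860, outside 4.16, naive 2.40, formative 5.19, germline 0.456, imprinted 2.67, haematopoietic 1.56, neuroectoderm 7.34, mesoderm and endoderm 3.33, primitive endoderm and trophoblast 1.44, Hox 8.42, machinery 0.830, 2-cell-like 1.65 and ubiquitously expressed 2.12. Of 66 such means 58 reversed, 3 weakened and 5 kept sign and side. Of 168 camera tests over all lists and contrasts 72 made a call with the preset correlation, of which 53 lost it with an estimated correlation, and of the 19 that held 9 were not called with an estimated correlation at the dense end of the gene. All 36 list means at the dense end of the gene kept direction and side, and of 420 called gene values 262 were also called there in the same direction, 0 in the opposite, 123 had the same sign uncalled and 35 the opposite sign uncalled. List medians were often smaller there, with 1.38 points on D0 and 0.625 on D2 for the naive list in TET_KO against TET_WT.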

Other observations

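The test of imprinted loci in this part was chosen after their values had been seen, and so were the genes named here. At the CpG-dense end of Peg3, an imprinted zinc finger gene, TET_WT held 18.9% ± 4.26 on D0 and 28.6% ± 8.95 on D2, TET_KO 6.50% ± 0.743 and 7.27% ± 1.04, and DNMT_WT 0.624% ± 0.587 and 5.71% ± 3.33. At the dense end of Meg3, a maternally expressed RNA gene, the values were 23.1% ± 2.28 and 43.6% ± 5.01 in TET_WT, 37.0% ± 6.61 and 46.7% ± 1.92 in TET_KO, and 5.17% ± 3.13 and 8.15% ± 1.70 in DNMT_WT. At that of Snurf, beside Snrpn, they were 21.2% ± 1.90 and 26.5% ± 8.96, 36.9% ± 3.44 and 38.8% ± 6.39, and 1.29% ± 1.84 and 3.85% ± 0.725.

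From these values came the hypothesis that imprinted loci regain less methylation in DNMT_WT than other CpG-dense ends, and it was examined on the same D2 values, which cannot decide it. The median D2 difference of DNMT_WT from TET_WT over 35 imprinted dense-end windows was -0.559 points, against 0.265 over sets matched on length and TET_WT level, a percentile of 0.4 among 10000 random sets. In camera the imprinted list at the dense end did not pass against other genes in this contrast, with adjusted p = 0.095, or adjusted p = 0.36 with an estimated correlation.

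Windows above 80% methylation made up 37.3% ± 5.18 of the genome on D2 in TET_KO, 2.53% ± 1.55 in TET_WT and 0.686% ± 0.137 in DNMT_WT. Windows below 5% made up 82.6% ± 0.868 on D0 in DNMT_WT, 6.66% ± 0.0307 in TET_WT and 3.95% ± 0.0264 in TET_KO. The 6 mitochondrial windows averaged 0.118% ± 0.0115 in TET_WT and 0.228% ± 0.0417 in DNMT_WT on D0.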
